A study of Mus musculus with 6 samples.

How the data were processed

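Messenger RNA was sequenced from cortical neurons of newborn Swiss mice after in utero electroporation of a control plasmid or of a plasmid with a sponge for miR-17-5p. Per the labels, total RNA was extracted with a column kit for small samples, and libraries were made from 50 ng of it with a stranded, ligation-based mRNA kit. Per the submitters' processing notes, the tools included STAR 2.7.6a and DESeq2 1.30.1 and the genome builds were mm10 and GRCm38. The gene annotation, the counting tool and its strand setting are not given in the sources used here.

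The deposited normalised counts are a signal on a linear scale: gene counts that the authors divided by 1 factor per library, named in the table's title as DESeq2 normalisation. In each of the 6 columns every value was a whole multiple of 1 step, with a largest gap of 9.546e-09 counts, and the sum of these multiples describes the depth, 115445910 to 138254412 counts per library. The raw counts were not used here, so no count model was fitted. The second deposited table is the authors' own comparison and gives for each gene the mean normalised count, a log2 fold change, a p-value and an adjusted p-value, per the file headers. Its means matched those of the count table to within 5.000e-05, and the direction of its fold changes was read from the count table. Its p-values are rounded by the authors to a few decimals.

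Samples were grouped by their titles into 3 control and 3 sponge libraries, and every column of the count table was matched to its sample by name. The tests, the alternatives, the 24 gene lists and the rule for naming genes were fixed before the data were examined. Of 35510 genes, the 22479 with a mean normalised count of at least 10 over the 6 libraries were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (limma-trend with robust empirical Bayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Fold changes are therefore on the log2(value + 1) scale, which understates changes of genes with low values. Gene lists were compared with all other tested genes by camera with a preset correlation between genes of 0.01, adjusted over the 24 lists, and again with an estimated correlation. The fry test asked whether the members of a list moved, on balance, in 1 direction. For each library, the score of a list is the median over its genes of the log2 value minus the gene's mean over the 6 libraries, and scores of the groups were compared by an exact two-sided permutation test, which cannot give a p below 0.1 with 3 against 3 libraries.

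Named genes were taken by 4 rules. The first takes, in each direction, genes past the threshold, filled up to 5 with the genes of smallest p, with a mean of at least 50 and no overlap between the groups, passing over predicted genes, symbols ending in Rik and symbols with "-ps". The second takes up to 4 genes of smallest p in each list. The third is a fixed set of Mir17hg and well known miR-17 targets, and the fourth is the 5 genes of smallest adjusted p in each direction in the authors' deposited table. Of the genes these rules take, those that matter most are given in the text. A gene of the third rule is not reported here.

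Gene positions, gene types and 3′ UTRs come from GENCODE release M21 on GRCm38, the same build as the authors'. Of the 35510 identifiers, 35389 were found there. The nuclear oxidative phosphorylation list had 25 tested entries because Atp5o has 2 identifiers, while Atp5f1a and Atp5f1b were not matched in the table. A seed match was the 7-base site GCACTTT or the 8-base site GCACTTTA in an annotated 3′ UTR of at least 50 bases. The shift of genes with a site is their median log2 fold change minus that of the other genes, tested by camera over the 15171 tested genes with such a UTR. As a reference, the shift was computed for 298 other words with the same bases as the 7-base site and for the sites of 10 other microRNAs, and site genes were matched 1 to 1 with other genes on UTR length and mean expression (within 0.25 SD).

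The fit was tested on simulated data for the comparison of sponge with control. With the spread of each gene as in the 6 libraries and 22479 genes run, it recovered 2% of 50 genes changed 1.5-fold, 36% of 50 changed 2-fold, 70% of 50 changed 4-fold and 94% of 50 changed 8-fold, with 3 false calls. With the spread seen when control library 1 was left out, the shares were 38%, 66%, 90% and 96%, with 5 false calls. This run still had 3 libraries in each group, so its shares do not describe the fit without control library 1. In each run the changed genes were drawn from those with a mean of at least 50. Each gene's simulated spread was the same in every library, whereas in the data control library 1 stood apart. The shares therefore do not give the power of the fit on the real libraries. With the spread of the 6 libraries, a simulated set shifted by 0.1 on the log2 scale had a camera p of 6.228e-05. Simulated genes varied independently of each other, so this p does not show how camera behaves on the correlated genes of a real list.

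The alternatives chosen at the same time were other pseudocounts (0.5 and 5), no filter or a mean of at least 50, TMM factors computed on the deposited values, quantile normalisation, a block for the replicate number, leaving out each library, a threshold of 0.1, other sites and backgrounds for the seed match, and lists without shared members. Array quality weights and a correction for transcript length, with and without control library 1, were added after seeing the data, as were 2 further lists used in the closing section. Count models were not run. Nothing in the labels states that the replicates come from separate litters beyond the pooling of brains, so the p-values measure the spread between these libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.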

Results

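The transcriptome of cortical neurons was measured on postnatal day 0 in mice of an outbred Swiss stock that had been electroporated in utero at E15.5. The electroporated plasmid was either a control or carried a sponge for miR-17-5p, a transcript with repeated binding sites that draws this microRNA away from its natural targets. There were 3 control and 3 sponge libraries, each from about 100000 cells of about 10 brains, and the deposited column names mark the cells as sorted by flow cytometry. Depth was similar, between 115445910 and 138254412 counts per library. The series is about prenatal alcohol exposure and connections between the hemispheres, and the comparison analysed here asks what holding back miR-17-5p does to gene expression in these neurons. The level of miR-17-5p itself was not analysed here.

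Immediate early genes, which neurons switch on within minutes of stimulation, stood higher in the sponge libraries than in the controls, with a median log2 fold change of 0.36 over 21 genes. Genes of the oligodendrocyte lineage also stood higher (median 0.29 over 12 genes), and so did BMP and TGF-beta signalling genes (median 0.12 over 23 genes). Interferon response genes stood lower (median −0.61 over 20 genes). These 4 lists passed the camera test in the same direction with and without control library 1. The number of lists called does not set the real groups apart. Of the 10 splits of the 6 libraries, 8 called at least as many as the 9 of the real split, itself included. Without 1 library in turn, the camera adjusted p ran from 1.282e-10 to 7.763e-04 for the immediate early genes, 1.002e-06 to 0.0110 for the oligodendrocyte lineage, 7.379e-04 to 0.0552 for BMP and TGF-beta and 1.558e-11 to 0.127 for interferon. The interferon median was −1.08 without sponge library 1 and −0.21 without sponge library 3. No list passed with an estimated correlation between genes, where the smallest adjusted p = 0.631.

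No single gene passed the test. With limma, 0 of 22479 genes were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.406. At an unadjusted p under 0.05 there were 356 genes higher and 294 lower, 650 in all against 1124 expected by chance. These counts rest on single libraries: they were 899 and 794 without control library 1, 870 and 329 without control library 3, and between 149 and 202 in each direction without any 1 sponge library. In 2520 genes (11.2%) the 3 sponge values did not overlap the 3 control values, where chance gives 10%. Adjusted over the list alone, 1 gene passed in the 24 lists together, Fos. With array quality weights, a setting chosen after seeing the data, limma called 3 genes higher and 1 lower (1108 and 636 at an unadjusted p under 0.05). The 95% interval of a fold change had a median half-width of 0.56 on the log2 scale. Without control library 1, 2 genes were called, both higher in the sponge: Fos (log2 fold change 0.83) and the pseudogene Capza1-ps1 (3.95, named after its values were seen).

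Control library 1 stood apart from the other 5 libraries. Its correlation with them across genes lay between 0.942 and 0.954, whereas the other pairs lay between 0.974 and 0.986, and the first principal component, with 52.8% of the variance, separated it from the rest. Its deviation from the other libraries fell with transcript length across 15171 genes (Spearman's rho −0.56, against 0.24 to 0.30 in the other libraries, whose reference includes control 1). Genes are not independent replicates, so these values describe the libraries. Haemoglobin transcripts made up 0.0253% of its counts and at most 0.0034% of those of the others, and its scores were the highest of the 6 for the erythroid list (2.42) and the microglia list (1.25).

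**Figure D1:**
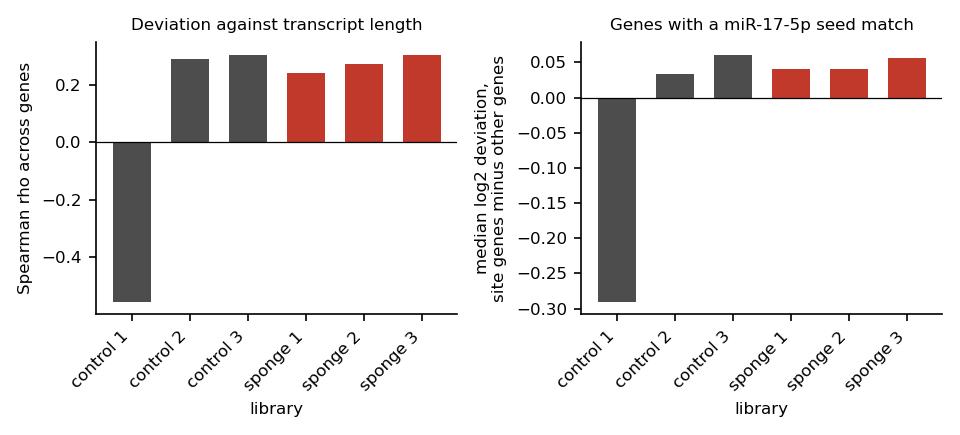
Left, Spearman's rho across genes between transcript length and each library's log2 deviation from the mean of the other 5. Right, median log2 deviation of genes with a miR-17-5p seed match minus that of the other genes. Control bars are grey and sponge bars red, and control 1 lies at −0.56 and −0.29 while the other 5 libraries lie above 0 in both panels.

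Among the immediate early genes, 18 of 21 were higher and 3 lower in the sponge libraries (camera adjusted p = 7.619e-07; adjusted p = 0.631 with an estimated correlation; fry p = 0.0216 unadjusted and 0.305 adjusted over the 24 lists). All 3 sponge scores (0.06, 0.33 and 0.17) lay above all 3 control scores (−0.11, −0.22 and −0.20; exact permutation p = 0.1, the smallest possible). Fos, a subunit of the AP-1 transcription factor (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), measured 12965 ± 1185 normalised counts in the sponge and 7954 ± 1230 in the control libraries (SD, n = 3 each), a log2 fold change of 0.71 ± 0.15 (SE; limma adjusted p = 0.925). Adjusted over the list alone, 1 gene passed, Fos (adjusted p = 0.0281), against 0 over all genes tested. Without control library 1 the values were 0.83 for Fos (adjusted p = 0.0399 over all genes), 1 gene over all genes and 7 genes adjusted over the list alone. The AP-1 partner Jun had a log2 fold change of 0.58 ± 0.16, and the zinc finger factors Egr1 and Egr2 had 0.54 ± 0.15 and 0.69 ± 0.24 (SE), none of them past the threshold. The 3 members on the lower side, named after their values were seen, were Ier5 (−0.10, and 0.12 without control library 1), Nr4a2 (−0.06, and −0.14) and Npas4 (−0.04, and −0.16).

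**Figure D2:**
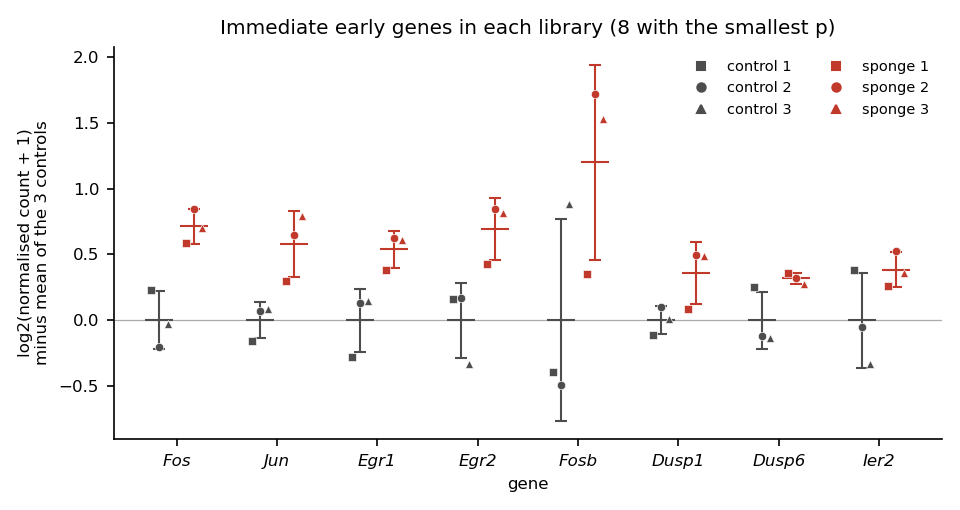
Log2(normalised count + 1) minus the mean of the 3 controls (vertical axis) for the 8 immediate early genes of smallest p (horizontal axis). Symbols are single libraries, horizontal bars group means and error bars SD (n = 3); for Fos, Jun, Egr1 and Egr2 every sponge library lies above every control library.

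All 12 genes of the oligodendrocyte lineage were higher in the sponge libraries (camera adjusted p = 9.393e-05; adjusted p = 0.656 with an estimated correlation), with 0 genes passing adjusted over the list alone and 1 without control library 1. Olig1, a transcription factor of oligodendrocyte precursors, measured 57997 ± 3540 against 45234 ± 3531 normalised counts (SD, n = 3 each; log2 fold change 0.36 ± 0.12, SE). The precursor receptor Pdgfra had 0.40 ± 0.15, and Lhfpl3 0.62 ± 0.22. The fry p of the oligodendrocyte list was 0.0665 unadjusted. Its scores were −0.35, 0.0224 and −0.23 in control libraries 1 to 3. Sponge libraries 1 to 3 had 0.0270, 0.23 and 0.20 (exact permutation p = 0.1), so control library 2 and sponge library 1 nearly coincided. Astrocyte markers had a median of 0.21 (adjusted p = 0.0745), with 9 members higher and 3 lower. The water channel Aqp4 was at 0.81 ± 0.24 and Aldh1l1 at −0.45 ± 0.26 (0.57 and −0.19 without control library 1). The astrocyte list passed without control library 1 (median 0.20, adjusted p = 0.00332, 4 genes adjusted over the list alone), without control library 2 (adjusted p = 0.0305) and without sponge library 3 (0.00379). Its median was 0.04 without sponge library 1 (adjusted p = 0.614) and 0.11 without control library 3 (0.799). Radial glia and intermediate progenitor genes had a median of 0.05 (adjusted p = 0.216) and passed without control library 1 (0.13, adjusted p = 0.0130) or sponge library 2 (0.09, adjusted p = 0.0164), but had a median of −0.0133 without sponge library 1 (adjusted p = 0.863). Neither list passed in all 6 libraries, and neither reached an adjusted p below 0.866 with an estimated correlation.

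Markers of other cell types differed less clearly. Interneuron genes stood lower, 17 of 20 members (median −0.22, camera adjusted p = 0.0140; adjusted p = 0.866 with an estimated correlation), with the transcription factor Maf at −0.48 ± 0.19. That call was lost without control library 1 (adjusted p = 0.233), without control library 2 (0.249) and without sponge library 1 (0.657), with medians of −0.07, −0.09 and 0.00131. The median was −0.36 without control library 3 and −0.44 without sponge library 3. Microglia (median −0.28, adjusted p = 0.389), vascular and meningeal cells (−0.01, 0.867), erythroid cells (−0.49, 0.3) and Cajal-Retzius cells (−0.12, 0.430) did not pass. Cell cycle genes did not pass either (median −0.04, adjusted p = 0.569). The vascular list passed in opposite directions without control library 1 (median 0.29, adjusted p = 0.00332) and without sponge library 1 (−0.07, 0.0481). Lower values passed for microglia without control library 3 (median −0.55, adjusted p = 0.0220) or sponge library 2 (−0.46, 0.0272). They also passed for erythroid cells without control library 2 (−1.43, 0.0106), and for cell cycle genes without control library 3 (−0.16, 0.00630) or sponge library 3 (−0.11, 0.0215). These 3 lists turned without control library 1, to medians of 0.31 for microglia (adjusted p = 0.0602), 0.47 for erythroid cells (0.0624) and 0.05 for cell cycle genes (0.530), and without sponge library 3 the microglia median was 0.12 (0.778). The Cajal-Retzius median ran from −0.27 without sponge library 2 to 0.0144 without sponge library 1.

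Targets of the miR-17 family from the literature, the transcripts that a sponge would release, stood higher over all 6 libraries in 38 of 50 cases (median 0.17, camera adjusted p = 0.00144; adjusted p = 0.866 with an estimated correlation). Without control library 1 the median was −0.01 and the adjusted p = 0.530, and without control library 2 the median was 0.26. No member passed adjusted over the list alone, and 1 did without control library 1, Tgfbr2. Tgfbr2, a receptor of TGF-beta (chromosome 9, 116084293 to 116175360), measured 605 ± 15.4 in the sponge and 413 ± 119 normalised counts in the control libraries (SD, n = 3 each; log2 fold change 0.59 ± 0.24, and 0.81 without control library 1). The guidance receptor Epha4 had 0.36 ± 0.14 and the BMP receptor Bmpr2 0.33 ± 0.17, and without control library 1 they had 0.23 and 0.16. The cell cycle inhibitor Cdkn1a (−0.02 ± 0.26), the kinase Mapk14 (−0.03 ± 0.12) and Stat3 (0.35 ± 0.19) did not pass. Cdkn1a had 0.28 and Mapk14 −0.10 without control library 1. Mir17hg, the host transcript of the microRNA cluster (chromosome 14, 115042879 to 115046727), measured 1001 ± 294 in the sponge and 1256 ± 455 in the control libraries (log2 fold change −0.31 ± 0.31, SE, and −0.53 without control library 1; limma adjusted p = 0.925).

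Across the transcriptome, 2024 of 15171 genes carried a miR-17-5p seed match in their 3′ UTR. Over all 6 libraries their median log2 fold change was 0.07, that of the other genes −0.02, and the shift between them 0.087 (camera p = 1.231e-04; p = 0.201 with an estimated correlation). Genes with the 8-base site shifted by 0.104, and by −0.00911 without control library 1. For all genes with a match the shift was −0.00912 without control library 1, and against genes matched on UTR length and expression it was 0.00599. It was 0.128 without control library 2 and 0.145 without control library 3. Genes with a site had a median UTR of 2400 bases against 883 bases for the others.

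Axon guidance genes were higher in 35 of 45 cases (median 0.12, camera adjusted p = 0.00144; adjusted p = 0.866 with an estimated correlation), and 0 passed adjusted over the list alone. The netrin receptor Dcc had a log2 fold change of 0.60 ± 0.19 and the Slit receptor Robo1 of 0.44 ± 0.23 (0.18 without control library 1). Without control library 1 the list's median was 0.04 and the adjusted p = 0.530, and without control library 2 the median was 0.21. Genes of upper-layer callosal neurons, which connect the hemispheres, had a median of −0.02 (adjusted p = 0.981), and those of deep-layer neurons −0.08 (adjusted p = 0.560). The axonal cytoskeleton and growth cone list (median −0.10, adjusted p = 0.135) and the synapse list (0.07, 0.569) did not pass, and the first of them passed as lower without control library 3 (−0.22, adjusted p = 0.00231) and turned to 0.03 without control library 1 (adjusted p = 0.820). Medians of the other lists that did not pass here ran from −0.03 without control library 1 to 0.14 without control library 3 (synapse), from −0.15 without control library 3 to 0.02 without control library 1 (deep-layer), and from −0.06 without control library 1 to 0.05 without control library 3 (upper-layer). Within the synapse list the kinase subunit Camk2b was at −0.40 ± 0.13 and the active zone protein Pclo at 0.61 ± 0.25 (0.31 without control library 1).

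BMP and TGF-beta signalling genes were higher in 16 of 23 cases (camera adjusted p = 0.00199; adjusted p = 0.656 with an estimated correlation; fry p = 0.0254 unadjusted and 0.305 adjusted over the 24 lists), 0 of them past the threshold adjusted over the list alone and 3 without control library 1. The ligand Bmp7 measured 2658 ± 144 against 1893 ± 200 normalised counts (SD, n = 3 each; log2 fold change 0.49 ± 0.14, SE), and the ligand Tgfb2 had 0.38 ± 0.12. The call was lost without control library 3 (adjusted p = 0.0552). Scores of the BMP and TGF-beta list were −0.12, −0.00735 and −0.14 in control libraries 1 to 3. Sponge libraries 1 to 3 had 0.16, 0.00132 and 0.12 (exact permutation p = 0.1), so control library 2 and sponge library 2 nearly coincided. Interferon response genes were lower in 19 of 20 cases (camera adjusted p = 1.340e-04; adjusted p = 0.866 with an estimated correlation). Their fry p was 0.341 unadjusted. Their scores overlapped between the groups, with 0.32, −0.23 and 1.06 in control libraries 1 to 3. Sponge libraries 1 to 3 had 0.40, −0.27 and −1.11 (exact permutation p = 0.4). Their members spread widely between libraries: the antiviral gene Ifit1 measured 61.7 ± 45.8 in the sponge and 277 ± 328 in the control libraries, and Usp18 192 ± 145 and 642 ± 682 (SD, n = 3 each). The call was lost without control library 3 (median −0.48, adjusted p = 0.127) and without sponge library 3 (−0.21, 0.0773), while the median was −1.08 without sponge library 1. The PI3K-AKT-mTOR list (median 0.11, adjusted p = 0.0675) and the p53 and apoptosis list (−0.02, 0.877) did not pass. The former passed as higher without control library 2 (adjusted p = 0.0107) and without control library 3 (0.0289), and its median was 0.00283 without control library 1 (0.753). The p53 and apoptosis median ran from −0.09 without control library 3 to 0.03 without control library 1.

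All 38 ribosomal protein genes were lower over all 6 libraries (median −0.25, camera adjusted p = 1.827e-04; adjusted p = 0.866 with an estimated correlation), and so were 24 of 25 entries for nuclear genes of oxidative phosphorylation (median −0.16, adjusted p = 0.0233; adjusted p = 0.912 with an estimated correlation). Both lists turned without control library 1, to medians of 0.16 (adjusted p = 5.728e-11) and 0.16 (adjusted p = 1.383e-08). The medians were −0.42 and −0.30 without control library 2, and −0.49 and −0.37 without control library 3. The ribosomal protein gene Rps24 measured 30969 ± 2291 in the sponge and 43838 ± 26630 normalised counts in the control libraries (SD, n = 3 each; log2 fold change −0.34, and 0.12 without control library 1). The nuclear list also lost its call without sponge library 2 (adjusted p = 0.0767) and without sponge library 3 (0.0636). Mitochondrially encoded genes did not pass (median −0.01, mean 0.12, adjusted p = 0.867), with medians from −0.08 without control library 2 to 0.12 without control library 3. The microRNA machinery, with the Argonaute genes, had a median of 0.11 (adjusted p = 0.389) and turned to −0.06 without control library 1 (adjusted p = 0.0141), while it passed as higher without control library 3 (0.25, adjusted p = 0.00914).

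**Figure D3:**
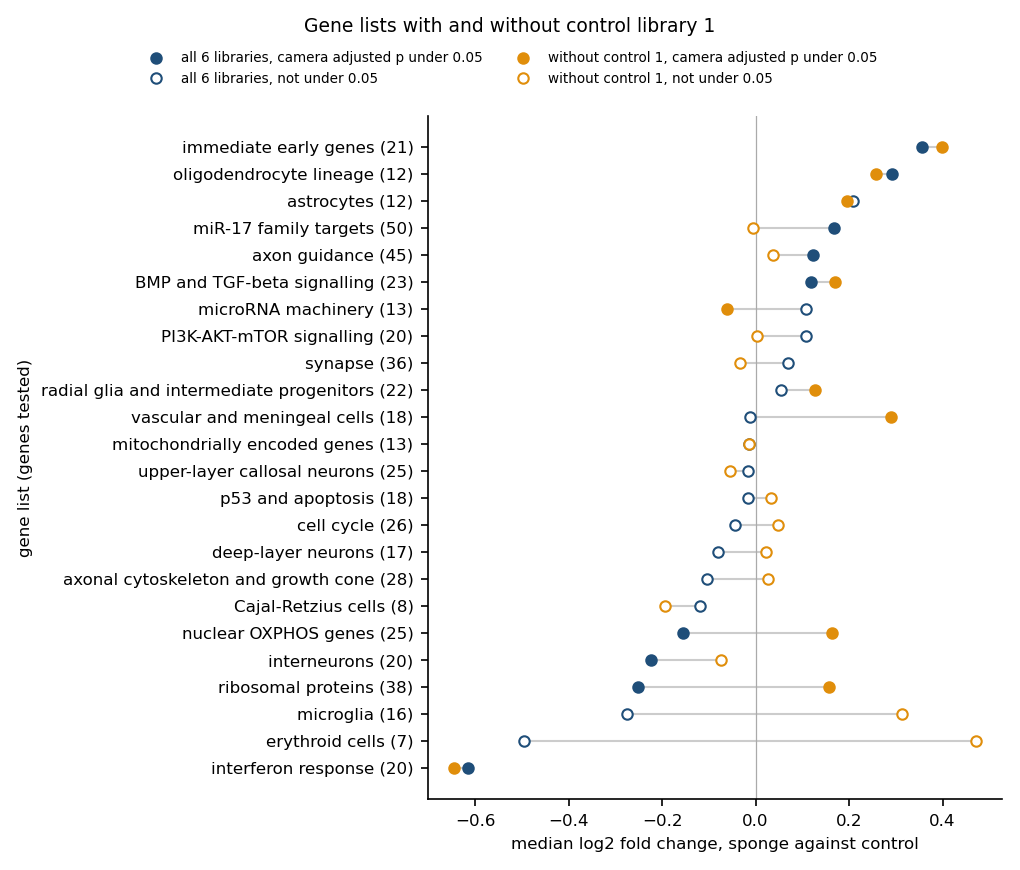
Median log2 fold change of sponge against control (horizontal axis) for each of the 24 gene lists (vertical axis, genes tested in parentheses), over all 6 libraries in blue and without control library 1 in orange. Filled circles have a camera adjusted p under 0.05 with the preset correlation; the immediate early, oligodendrocyte lineage, BMP and TGF-beta and interferon lists are filled in both colours on the same side of 0.

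Predicted genes and symbols ending in Rik or with "-ps" passed over, the single genes with the smallest p among those with a mean of at least 50 and no overlap between the groups did not pass over all genes either. In the higher direction these were Zfp125, Rps3a3, Fos, H2-T24 and Fndc1, and in the lower direction Minar2, Klrb1, Tmem249, Pik3cd and Sbsn. Minar2 (ENSMUSG00000050875, chromosome 18, 59062248 to 59076962) measured 3342 ± 149 in the sponge and 5349 ± 502 normalised counts in the control libraries (SD, n = 3 each), a log2 fold change of −0.68 ± 0.12 (SE). Pik3cd, a catalytic subunit of PI3 kinase (chromosome 4, 149649168 to 149702571), measured 790 ± 84.5 and 1321 ± 143, a log2 fold change of −0.74 ± 0.17. Both had a limma adjusted p of 0.925. Klrb1, a receptor of lymphocytes, was listed at 0 in sponge libraries 2 and 3 and at 11.8 in sponge library 1, against 34.7 to 205 in the controls. Fndc1, a fibronectin domain gene, had 666 ± 32.8 against 346 ± 89.3 normalised counts.

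The authors' deposited table held 10812 genes, all with a mean normalised count above 1000, and 1 of them had an adjusted p under 0.05. That gene was Rps3a3, an annotated processed pseudogene (chromosome 13, 108670603 to 108671397), with a log2 fold change of 6.48 and an adjusted p of 1.000e-04 in the authors' deposited table. In the limma fit it had 5.96 ± 1.03 (SE) and an adjusted p of 0.925. It stood at 447 normalised counts in sponge library 1, 6256 and 6392 in the other sponge libraries, and 22.3 to 91.0 in the controls, and since such a copy shares sequence with its parent gene its reads are uncertain. Next in the authors' deposited table came Minar2 (adjusted p 0.103), Fos and Pik3cd (both 0.272). Junos, also among the first in that table, overlaps Jun on the opposite strand, and the strand setting of the counting is not given in the sources used here. Of the 10812 genes, 97.5% had the same sign in the authors' deposited table and in the limma fit, with a Pearson correlation of 0.974 across genes.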

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

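Array quality weights and the transcript length correction were chosen after seeing the data; the planned edgeR, DESeq2 and voom fits on recovered reads were not run. Pseudocounts, filters, TMM factors, quantile normalisation, a threshold of 0.1 and non-robust moderation all left 0 genes called, and no scaling moved the median of all genes by more than 0.02. Leaving out each library gave 0 to 2 genes higher, 5 to 8 lists higher, 2 to 6 lists lower and a seed-match shift of −0.00912 to 0.145. Adjusted p over these ranged from 0.00332 to 0.772 (vascular and meningeal), 0.00914 to 0.554 (microRNA machinery), 1.383e-08 to 0.0767 (nuclear oxidative phosphorylation) and 5.728e-11 to 0.00493 (ribosomal proteins), each turning direction without control library 1. Array quality weights gave control 1 a weight of 0.126 and called 3 genes higher (Capza1-ps1, Zfp125, Fos) and 1 lower (Minar2). The vascular (0.0239), nuclear oxidative phosphorylation (0.0582) and ribosomal (0.264) lists turned under them, and the shift was 0.014. The length correction over all 6 libraries gave a shift of 0.0064, ended 4 list calls and added 3. With the length correction and without control library 1 the shift was −0.00622, with 2 genes higher, 8 lists higher and 2 lower. The lists just named were then at 0.00248 (vascular), 0.00630 (microRNA machinery), 2.046e-06 and 4.706e-09. The estimated correlation and fry each left 0 lists higher and 0 lower, and the shift of 0.087 then had p = 0.201. Against matched genes the shift was 0.00599. The ribosomal, nuclear oxidative phosphorylation, miR-17 target and axon guidance calls over all 6 libraries rested on control library 1. Its scores were 0.93, 0.79, −0.31 and −0.41 in these lists, in that order. The other libraries had −0.36 to −0.00145, −0.30 to −0.00954, 0.04 to 0.08 and 0.02 to 0.14. The interneuron score of control library 1 (0.33) lay near that of sponge library 3 (0.31). Why control library 1 departed, and the cause of the other lost and turned list calls, was not tested. The immediate early and oligodendrocyte lists kept their call under the alternatives other than the estimated correlation and fry (immediate early: adjusted p 1.197e-12 to 0.000776). A change of sign between values that both missed the threshold was not counted as a reversal; it occurred in 17 of 114 named genes without control library 1, 11 with array weights and 5 with the length correction (17 with both changes), 1 to 3 without another library and 0 elsewhere. The replicate block called 0 genes, 6 lists higher and 4 lower, and a shift of 0.087. The replicate numbers showed no pairing: deviations of same-numbered libraries correlated at 0.0096, 0.0054 and −0.053, and 1 of 3 controls correlated best with its own number. This cannot exclude a pairing. The deviations were taken within each group, and the departure of control library 1 weighs on those of all 3 controls. Depth was similar across libraries, and the median half-width of the intervals was 0.56 with and 0.36 without control library 1.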

Other observations

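The tests of control library 1, of target release and of matched genes as sources of the seed-match shift, and the count of genes with exactly 1 library apart, were chosen after the result was seen. Of the 18002 genes with a mean normalised count of at least 50, 11 stood at least 4-fold apart between the groups with no overlap, and 6 of these were annotated pseudogenes; the other splits of the 6 libraries had 3 to 20 such genes, so a count of 11 is not unusual here. These genes were singled out after their values were seen. Capza1-ps1 (chromosome 1, 105455971 to 105458829), a copy of an actin capping protein gene, stood at 951 to 1080 normalised counts in the sponge libraries and at 50.6 to 148 in the controls (log2 fold change 3.55 ± 0.38, SE; limma adjusted p = 0.406, and 9.535e-05 without control library 1). Zfp125 and the overlapping 3110053B16Rik on chromosome 12, Gm10059 and Mdm4-ps were also higher in the sponge libraries. H2-T24, a class I histocompatibility gene, stood at 90.7 to 141 against 10.0 to 42.1, and Tmem249 at 7.29 to 41.4 against 98.1 to 136.

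For the shift of genes with a seed match, release of targets by the sponge was tested against library and sequence effects. Without control library 1 the shift was −0.00912, and it lay at percentile 2.01 of the words of the same bases, which argues against release of targets as the source of a shift of 0.087, though a smaller release stays open. The tables are consistent with the departure of that library, which lowers long transcripts (site genes at −0.29 in control 1, 0.03 and 0.06 in the other controls, 0.04 to 0.06 in the sponge libraries), and with UTR length and expression, since the shift against matched genes was 0.00599. Over all 6 libraries the shift lay at percentile 95.3 of those words; the bound set beforehand was the 95th percentile, but the excess of 1.246e-04 is smaller than the words' SD of 0.0088, so after that value was seen it was left as undecided. With 10 splits of the 6 libraries no share can fall under 0.05: the real shift of 0.087 stood against 0.097 as the highest other, and 6 of the 10 splits gave one as large.

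For the immediate early genes, 2 lists were drawn up after the pattern was seen and before their own values were known. Heat-shock genes that tissue dissociation induces had a median log2 fold change of 0.00589 (14 genes), so a stress of dissociation and sorting finds no support there but stays open, because these genes need not move with the immediate early ones. Late-response genes of neuronal activity had a median of −0.27 (13 genes), with quartiles of −0.53 and −0.11 and a camera p of 0.0291 for lower values, and met the bound set beforehand against higher activity (at or below 0, and at most 0.1 without any 1 library, the highest being −0.11); these values go against higher activity, but that bound ignored the spread between libraries, and since the scores differed by −0.16 ± 0.25 (SE; exact permutation p = 0.6), it was left undecided after the values were seen. More glial cells could raise glial markers, whose upper quartile of 0.40 lies above the immediate early median of 0.36 while their own median of 0.25 lies below it, and this cannot be told apart because the values straddle the bound. A response to the sponge also stays open as untested.

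For the pseudogenes, inherited differences between pools of outbred animals are a candidate explanation. Pseudogenes were also over-represented among genes in which at least 1 library stood at least 4-fold away from each of the others (odds ratio 2.12, Fisher's exact p = 5.029e-04), although 340 of those 374 genes come from control library 1 alone and 6 have more than 1 library apart; over the other 34 genes the odds ratio was 3.43 (95% interval 0.88 to 9.78, which includes 1) and over the 28 of them with exactly 1 library apart 4.29 (1.08 to 12.5), with 1 of the 4 pseudogenes from control library 2, 3 from control library 3 and 0 from the sponge libraries. These Fisher tests did not match genes on expression or transcript length, so an odds ratio above 1 cannot by itself point to inherited differences. Reads shared with the parent gene stay open as a further source. The change of the pseudogene was a median of 6.46% of its parent's level over 6 pairs (0.20 to 14.6%), an amount the parent could supply. A copy with far fewer counts than its parent would give a small percentage whatever the cause, so this cannot decide. Only Capza1-ps1, Rps3a3 and Mdm4-ps of these pairs are among the 11 genes. A response to the sponge stays open: 6 such pseudogenes parted the real groups and at most 3 parted any other of the 10 splits, which are too few for a share under 0.05. Among these 6, Zfp125 and 3110053B16Rik overlap on chromosome 12, so they need not be independent of each other.

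The number of splits also limits the other counts. The real split called 0 genes, a count that every one of the 10 splits reaches, so this comparison tests nothing; the highest other called 1. It called 9 lists where the highest other called 14, with 8 of 10 splits giving at least as many. Every split holds control library 1 on 1 side.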
